A study of Mus musculus with 10 samples.

How the data were processed

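ATAC-seq, in which a transposase cuts accessible DNA and tags it for sequencing, had been applied to nuclei from the left and right atria of mice aged 8 to 12 weeks. Per the labels' protocols, the atria of each animal were pooled, nuclei were stained for PCM1, a protein that marks cardiomyocyte nuclei, and stained nuclei were sorted by flow cytometry. Fragments were read as pairs of 150 bp. There were 10 libraries. The control group had 6 libraries from 4 animals, because animals 1 and 3 each had a repeat library, and the Prrx1(R1A)-/- group, called R1A-deleted here, had 4 libraries from 4 animals. The series title speaks of a noncoding region that regulates Prrx1, and the sequence bounds of the allele are not given in the sources used here.

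The submitters' processing notes name BWA, bedtools and DESeq2, without versions or roles, and the mouse build mm10. Per the file headers, the deposited table lists merged regions, each with 1 bin of 500 bp that stands for it, and gives read counts of that bin. The authors' deposited counts are raw read counts in all but 17 cells, where 0.1 is written and no cell holds 0. Because of these cells the authors' columns were handled as estimated counts, and 0.1 was rounded to 0 for the count tests. The authors' deposited log2 fold change is control over R1A-deleted, and its sign was turned here so that a positive value means more reads in the R1A-deleted group. The deposited p-values are adjusted p-values of the authors' comparison, with a highest value of 0.04999. The deposited group signal, a geometric mean of the raw counts over the group's libraries, matched the count columns with a largest relative difference of 7.8e-10. The filter on bins, the design of the authors' test and its treatment of the repeat libraries are not given in the sources used here. How reads were shifted for the transposase cut, and how duplicates were handled, are not given either.

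The table lists only regions that the authors called, 5327 in all. Unchanged regions and total reads per library are not in it, so nothing can be said of how called regions compare with unchanged ones. The reads in listed bins ranged from 151976 to 521778 per library, which is not the sequencing depth. Counts of called regions, their directions and their order by fold are the authors'. The repeat libraries of controls 1 and 3 differed by more than sampling noise (chi-square per degree of freedom 1.83 and 1.7, against 2.17 to 3.4 between different control animals), and were summed per animal, giving 4 animals against 4.

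Levels per animal and their errors were computed from the counts. The fit planned before the data were examined was edgeR 4.0.16 under R 4.3.3 (glmQLFit and glmQLFTest) with TMM factors, the filterByExpr filter, which removed 0 regions, and Benjamini-Hochberg adjustment at 0.05. TMM assumes that most regions do not change, which cannot hold in a table of called regions. A second scale, added after the data were seen, was therefore taken from the authors' own fold changes. Their log2 fold change was regressed on the log2 ratio of the deposited geometric means over 1432 regions with both means at or above 50. The fit had a slope of 0.874 and set the difference in scale between groups at 0.142 log2 (95% bootstrap interval 0.14 to 0.144). Factors within a group were median ratios. On this scale, called the authors' scale, log2 fold changes were 0.60 higher than with TMM. Scaled counts and edgeR log2 fold changes given for named regions are on the authors' scale, and are larger in size than the deposited ones for many regions. All p-values of these fits are for regions already selected by the authors on the same libraries, so they are not independent evidence. In simulated counts for 5327 regions with 4 animals per group, the edgeR step recovered 37.3% of 67 regions changed 1.5-fold, 82.1% of 67 changed 2-fold and 100% of 66 changed 3-fold, with 9 false among 155 calls. The simulation left most regions unchanged and used TMM factors. Its rates therefore do not carry over to a table of called regions or to the authors' scale.

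Each bin was assigned to the nearest protein-coding gene body among 21900 in the RefSeq table of assembly GRCm38.p6, the same coordinates as mm10. That table has no strand, exons or sequence, so exonic or intronic position is not given, distance to a start site was replaced by distance to the nearer gene end, and the planned motif counts were not run. Distances are from the bin, except those to Prrx1, Fkbp5 and microRNA genes, which are from the region's edge. Assignment to the nearest gene does not show that a region acts on that gene. Gene lists were fixed before the data were examined: Prrx1 locus genes, sarcomere, ion channels, calcium handling, cardiac transcription factors, atrial fibrillation loci, atrial, ventricular, fatty acid and mitochondrial metabolism, stress and immediate early response, TGF-beta with BMP and Wnt signalling, junctions, sex-linked genes, and markers of fibroblasts, endothelium, smooth muscle, immune cells, epicardium, neural cells and adipocytes. For each list, the split of higher and lower regions was set against all other listed regions with a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists. List odds ratios have a small constant added to each count, which shapes them where counts are very small. Regions of a gene are not independent, so a permutation that draws random genes was added after the data were seen. Genes were matched in coarse classes of their number of listed regions, and a list's own genes were not left out of the draws. The small top class ran from 10 regions (Svil) to 43 (Myo18b) per gene.

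Named regions followed a rule fixed before the data were examined. It takes regions within 500 kb of Prrx1, the 10 largest authors' fold changes per direction among bins at or above the median mean count of 49.2 with 1 per gene, up to 4 genes per list with the smallest adjusted p, and the 5 genes with the most regions. Other genes named by their number of regions alone were chosen after their values were seen. Results for some genes are not reported here. Errors are SD over 4 animals for scaled counts and standard errors for edgeR log2 fold changes. Intervals on read totals and shares are exact 95% intervals and cover counting error only. Alternatives covered the threshold, a fold filter, low counts, sex chromosomes, regions near Prrx1, scaling, RLE factors, DESeq2 1.42.0, repeat libraries kept apart, a block on animal number, each animal left out, gene assignment and windows. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps.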

Results

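Accessible chromatin of sorted atrial cardiomyocyte nuclei was compared between 4 control mice and 4 mice homozygous for the Prrx1(R1A) allele. Prrx1 encodes a paired-related homeobox transcription factor, and the human gene lies at a locus associated with atrial fibrillation. The comparison asks where accessibility differs when the noncoding region is altered. The authors listed 5327 differential regions with a median width of 750 bp (500 to 16000), of which 60.9% had their bin inside a protein-coding gene and 85.0% within 50 kb of one. They were nearest to 3149 genes.

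At the targeted locus, reads were nearly lost. Within 500 kb of Prrx1 (mm10 chromosome 1, 163245119 to 163315145) there were 2 listed regions, both in the intergenic stretch past the gene's higher-coordinate end and both lower in R1A-deleted atria. The region at 163327001 to 163328000, 11.9 kb from the gene, had 54.8 ± 4.14 scaled reads in controls and 1.49 ± 1.74 in R1A-deleted animals (SD, n = 4 each). Its bin held 284 reads over the controls and 5 over the R1A-deleted animals, of which animals 2 and 3 had 0. After scaling, R1A-deleted reads were 2.4% of control (exact 95% interval 0.8 to 5.7). The region at 163337501 to 163339000, 22.4 kb from the gene, had 56.9 ± 20.7 scaled reads in controls and 3.45 ± 1.27 in R1A-deleted animals (SD, n = 4), or 6.0% of control (3.2 to 10.5). In the authors' deposited table these were the 2 lowest log2 changes of all, -2.94 (adjusted p = 3.50e-25) and -2.43 (adjusted p = 5.11e-17). No listed region lay inside Prrx1, and none was nearest to another gene of the Prrx1 locus list. Widening the window to 1000 kb gave 5 regions, the added ones being higher and nearest to Slc19a2 or Eef1aknmt. The bounds of the allele are not given, so these reads do not separate absent sequence from lost accessibility, and the reads that remained are unexplained.

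Across the genome, R1A-deleted atrial cardiomyocytes gained reads at 3551 listed regions and lost them at 1776. Typical higher regions went from 39.0 to 80.8 scaled reads and typical lower regions from 65.5 to 31.8 (medians over regions). All 4 R1A-deleted animals lay beyond all 4 controls at 90.6% of higher and 88.8% of lower regions, against 1.4% by chance in a given direction, although regions had been selected for their difference. In the authors' deposited table the median log2 change was 0.81 for higher and -0.80 for lower regions. Higher regions made up 66.7% (exact 95% interval 65.4 to 67.9; two-sided exact binomial p = 5.6e-133, which treats regions as independent). This split moves with the scaling, but neither scale tests it. With TMM factors on the listed regions, edgeR called 988 higher and 1776 lower, or 35.7% higher, and turned 154 regions. TMM shifts a mostly higher table downward, so losing higher calls while keeping lower ones was built in. The authors' scale gave 3551 and 1776, but it was fitted to the authors' own fold changes. With TMM, leaving out R1A-deleted animal 1 or 2 cut the higher calls to 606 or 625.

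**Figure D1:**
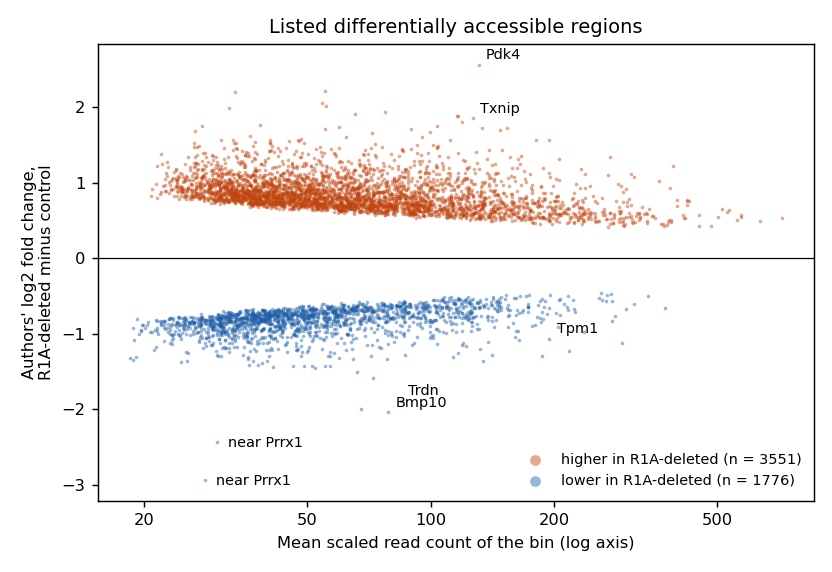
Each point is a listed region, with the mean scaled read count of its bin on a log axis and the authors' log2 fold change, R1A-deleted minus control, on the vertical axis; orange points are the 3551 higher and blue points the 1776 lower regions. The 2 regions near Prrx1 lie lowest, at -2.94 and -2.43, and the region at Pdk4 lies highest, at 2.56.

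The largest gain was at Pdk4. A region of 16000 bp over Pdk4 (chromosome 6, 5479751 to 5495750), the kinase that shuts off pyruvate dehydrogenase, rose from 19.6 ± 8.97 to 242 ± 109 scaled reads (SD, n = 4), a log2 change of 3.48 ± 0.27 (SE; edgeR adjusted p = 1.71e-09). A region spanning Txnip (chromosome 3, 96554501 to 96565000), whose product restrains glucose uptake, rose by 2.47 ± 0.25 log2 (SE; edgeR adjusted p = 1.78e-08), from 36.0 ± 15.0 to 218 ± 89.6 scaled reads. A region across Ucp2 and Dnajb13 rose by 2.13 log2, and one inside Bpgm, which makes the red cell metabolite 2,3-bisphosphoglycerate, by 2.16. The others among the 10 largest gains by the authors' fold, taken from bins at or above the median count with 1 per gene, were inside Sulf2 (2.26), Usp25 (2.19) and Gm826 (2.18), 87.5 kb from Foxk1 (2.42), 17.6 kb from Armc12 (2.39) and 77.4 kb from Ets1 (1.98).

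Away from Prrx1, the largest losses were near Bmp10 and Trdn. A region 9.7 kb from Bmp10 (chromosome 6, 87417251 to 87419750), a growth factor made by atrial myocytes, fell from 133 ± 37.1 to 23.95 ± 2.88 scaled reads (SD, n = 4), a log2 change of -2.43 ± 0.22 (SE; edgeR adjusted p = 3.8e-09). A region inside Trdn (chromosome 10, 33199751 to 33209000) fell from 138 ± 19.99 to 31.2 ± 7.5 scaled reads, a log2 change of -2.18 ± 0.20 (SE; edgeR adjusted p = 6.13e-09). A region with a log2 change of -1.86 lay 52.7 kb from Slco4a1 and beside the microRNA gene Mir133a-2, 0.3 kb away, with Mir1a-1 at 9.6 kb. Both microRNAs are muscle-specific. The others among the 10 largest losses, taken in the same way, were inside Dcdc2a (-1.77), Tpm1 (-1.57) and Olfml2b (-1.55), and at a distance from Stag2 (-1.78), Anxa10 (-1.74), Gdf6 (-1.73) and Cyria (-1.69).

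Regions near calcium handling genes were mostly lower, 72 against 21 higher (odds ratio 0.143, adjusted p = 3.6e-17, Fisher's exact test). The losses concentrated at 4 genes of the sarcoplasmic reticulum. Atp2a2, the calcium pump, had 20 lower and 1 higher region, Jph2, which ties the reticulum to the surface membrane, 17 lower, Trdn, which anchors the calcium store protein to the release channel, 15 lower, and Ryr2, the release channel itself, 15 lower and 6 higher. Of these regions 1 lay far from its gene, at 565.1 kb from Ryr2 (-1.54 log2). The Jph2 region at chromosome 2, 163350751 to 163354750, fell from 314 ± 71.0 to 120.2 ± 8.5 scaled reads and that inside Atp2a2 (chromosome 5, 122461501 to 122465750) from 217 ± 13.0 to 106 ± 13.3 (SD, n = 4). Pln had 2 lower regions, whereas Itpr1 had 5 higher and Atp2a1 had 2 higher. Of the 13 list genes with a listed region, 5 had only higher, 4 only lower and 4 both. Against random genes from the same classes of region number the list was not called (adjusted p = 0.2 by permutation). Atp2a2, Jph2, Trdn and Ryr2 themselves stand in the small top class that was drawn from, which limits this test. The list was not called with 1 region per gene either (adjusted p = 0.7, Fisher's exact test).

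The atrial program was mostly lower as well, with 56 lower and 11 higher regions (odds ratio 0.0989, adjusted p = 1.9e-16, Fisher's exact test), and this held against random genes (adjusted p = 0.012 by permutation). Of its 13 genes with a listed region, 8 had only lower ones. Pam, the enzyme that amidates peptide hormones and is abundant in atrial granules, had 32 lower regions and none higher. Kcnj3, a subunit of the acetylcholine-activated potassium channel, had 7 lower, Bmp10 3, Dkk3 3, Nppb 2 and Nppa, the atrial natriuretic peptide, 1. The Nppa region (chromosome 4, 148000751 to 148002750) went from 282 ± 12.3 to 167 ± 17.8 scaled reads (SD, n = 4), a log2 change of -0.76 ± 0.13 (SE; edgeR adjusted p = 2.4e-05). Myl4, the atrial light chain, had 5 lower and 1 higher region, and Tbx5 2 lower. Stard10 went the other way with 6 higher regions, as did Kcna5 with 2. Without Pam the odds ratio was 0.228 (adjusted p = 7.2e-05, Fisher's exact test). With 1 region per gene it was 0.219, which did not pass (adjusted p = 0.084), nor did the few regions within 1 kb of a gene end (0.108, adjusted p = 0.061). The permutation was not run without Pam. Pam itself stands in the small top class that was drawn from, which limits the permutation here too.

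Sarcomere genes split by gene. There were 56 lower and 40 higher regions (odds ratio 0.351, adjusted p = 3.1e-06, Fisher's exact test), with 13 genes only lower, 12 only higher and 3 both, and the list was not called against random genes (adjusted p = 0.23 by permutation) or with 1 region per gene (adjusted p = 0.2). Actn2 and Tpm1 had 8 lower regions each, Fhl2 7, Actc1 and Ldb3 5 each and Ankrd1 4, with none higher. Ttn, which encodes the giant protein titin, had 14 higher regions and none lower, and Myom2 had 3 higher. A Tpm1 region (chromosome 9, 67044251 to 67050000) went from 269 ± 34.9 to 120.4 ± 20.8 scaled reads (SD, n = 4). A region in Smyd1, a muscle methyltransferase, changed by -0.95 log2.

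Ion channel and conduction genes had 39 lower and 31 higher regions (odds ratio 0.394, adjusted p = 0.00052, Fisher's exact test), but with 1 region per gene the direction turned (odds ratio 1.23, adjusted p = 1), and against random genes the adjusted p was 0.72 by permutation. Gja1, which encodes connexin 43, had 8 lower and 2 higher regions, Cacnb2 8 lower and 2 higher, and Kcnd2 5 lower and 1 higher. Kcnk3 had 3 higher regions and Cacna1c 7 higher and 5 lower. The region 0.5 kb from Cntn2 rose by 1.11 ± 0.22 log2 (SE) on the authors' scale and was not called with TMM (0.51, edgeR adjusted p = 0.053).

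Cardiac transcription factor genes had 29 lower and 27 higher regions (odds ratio 0.462, adjusted p = 0.011, Fisher's exact test), a call lost without Myocd (odds ratio 0.634, adjusted p = 0.31) and against random genes (adjusted p = 0.2 by permutation). Myocd, the coactivator of serum response factor, had 8 lower regions, Gata5 4 and Etv1 3. Mef2d had 4 higher, and Mef2c and Tbx3 3 higher each. Many of these regions lay far from their gene: within 50 kb there were 12 lower and 18 higher (odds ratio 0.683, adjusted p = 0.62, Fisher's exact test). The region assigned to Gata5 (57.5 kb away; chromosome 2, 180391001 to 180395750) changed by -1.44 log2. It lay between the microRNA genes Mir1a-1 and Mir133a-2 named above. The region nearest to Prox1 (194.2 kb away) changed by 1.75. Ppargc1a, a coactivator of mitochondrial genes, had 4 lower regions and 1 higher.

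Genes at human atrial fibrillation loci showed no lean of their own: 58 regions were higher and 29 lower, or 66.7%, against 66.7% of all other regions (odds ratio 0.992, 95% interval 0.635 to 1.55, adjusted p = 1, Fisher's exact test). Besides Ttn, the higher regions included 12 at Nav2 and 5 at Sox5, and the lower ones 8 at Gja1. Regions inside Igf1r (1.27), Sox5 (1.13) and Rpl3l (1.01) were higher on the log2 scale.

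Stress and immediate early genes were mostly lower, 24 against 11 (odds ratio 0.232, adjusted p = 0.00015, Fisher's exact test; adjusted p = 0.016 by permutation against random genes). With 1 region per gene the call was lost (odds ratio 0.242, adjusted p = 0.084). Members with lower regions included natriuretic peptide, growth factor and heat shock genes. Ankrd1 and Tgfb2 had 4 lower regions each, Ccn2 3, and Nppb, Hspa1b and Dnajb1 2 each. A region of 7500 bp over Ccn2, a matrix protein induced by TGF-beta (chromosome 10, 24593001 to 24600500), fell from 412 ± 70.8 to 175 ± 13.7 scaled reads (SD, n = 4), a log2 change of -1.22 ± 0.13 (SE; edgeR adjusted p = 7.02e-08). Of the immediate early genes, Myc had 4 higher and 1 lower region, Jun 3 higher and Fos 1 higher, while Nr4a1 had 1 lower.

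TGF-beta, BMP and Wnt signalling genes had 18 lower and 7 higher regions (odds ratio 0.201, adjusted p = 0.00047, Fisher's exact test; adjusted p = 0.012 by permutation against random genes). With 1 region per gene the call was lost (odds ratio 0.408, adjusted p = 0.35). Tgfb2 had 4 lower regions, Bmp10 and Dkk3 3 each, Bmp2 and Smad7 2 each, and Bmp4 and Wnt5a 1 each. Higher regions were single ones near Id2, Id3, Smad3, Smad6, Tcf7l2, Tgfbr2 and Axin2. The Id2 region (136.9 kb from the gene) rose by 1.78 ± 0.16 log2 (SE), and those of Tgfbr2 and Axin2 by 1.13 and 0.90, the last not called with TMM (0.31, edgeR adjusted p = 0.075). Bmp10, Dkk3, Nppa, Nppb and Tgfb2 each stand in more than 1 of these lists, so the lists are not independent.

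Genes of fatty acid and mitochondrial metabolism were higher at 45 regions and lower at 14, which did not pass the test (odds ratio 1.58, adjusted p = 0.24, Fisher's exact test; adjusted p = 0.72 by permutation), although it did among regions with an authors' adjusted p under 0.01 (odds ratio 3.64, adjusted p = 0.022). Of 19 genes, 14 had only higher regions. Cpt1a and Cpt2, the carnitine palmitoyltransferases of fatty acid import, had 7 and 2 higher, the fatty acid carrier Slc27a1 5, Acsl1, Pdk4 and Ucp3 4 each, and Cd36, Acot2 and the lipase inhibitor Angptl4 3 each. The region over Angptl4 (chromosome 17, 33777751 to 33782750) rose from 82.8 ± 7.7 to 278 ± 52.5 scaled reads and that in Cpt2 (chromosome 4, 107921251 to 107922750) from 39.3 ± 13.5 to 146 ± 17.9 (SD, n = 4), with log2 changes of 1.76 and 1.79. The Acot2 region rose by 2.02 log2. Lower regions were at Ckm and Ogdh (3 each), Atp5a1 (2), Ppargc1a and Mb.

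**Figure D2:**
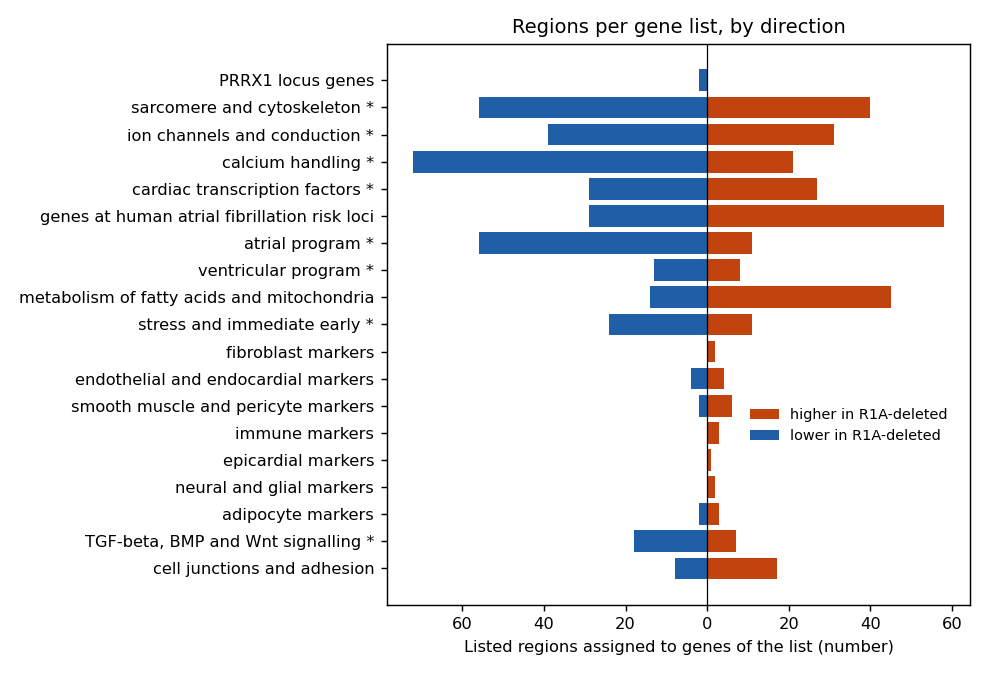
Bars give the number of listed regions assigned to genes of each list, higher in R1A-deleted to the right and lower to the left, and an asterisk marks lists with an adjusted p under 0.05 by Fisher's exact test over regions. Calcium handling (72 lower, 21 higher) and the atrial program (56 lower, 11 higher) lean furthest to the left, while metabolism (45 higher, 14 lower) leans to the right without passing the test.

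Markers of other cell types had few listed regions, 29 over the 7 lists, of which 21 were higher. Fibroblast markers had 2, both higher (Dpt and Fbln1), immune markers 3 higher (Runx1 and Csf1r), neural and glial markers 2 higher (Foxd3 and Snap25) and epicardial markers 1 higher (Krt8). Smooth muscle and pericyte markers had 6 higher and 2 lower, with Acta2 lower (-1.28) and Cspg4, Pdgfrb and Des higher. Endothelial and endocardial markers had 4 higher, among them Erg (1.51), and 4 lower, among them Npr3 (-1.79) and Kdr (-0.96). Adipocyte markers had 3 higher, at Pparg and Lep, and 2 lower, at Adipoq and Fabp4. None of these lists was called, with adjusted p from 0.75 to 1 by Fisher's exact test. The higher regions of Fbln1, Pdgfrb, Cspg4, Des, Csf1r, Krt8, Snap25, Pparg and Lep were not called by edgeR with TMM.

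Ventricular genes had 13 lower and 8 higher regions (odds ratio 0.313, adjusted p = 0.021, Fisher's exact test), a call lost against random genes (adjusted p = 0.51 by permutation) and without Fhl2 (odds ratio 0.651, adjusted p = 0.88). Fhl2 had 7 lower regions, Myh7 and Lmod2 2 each and Myl2 1, while Cpne5 had 5 higher and Hspb7 3. Junction genes had 17 higher and 8 lower regions (odds ratio 1.03, adjusted p = 1, Fisher's exact test), among them Dmd with 4 higher and 1 lower, and Jup with 3 higher. Dsc2 (0.83) and Jup (0.83) were higher on the log2 scale but not called by edgeR with TMM, and a Pkp2 region was lower (-0.81). The Prrx1 locus list had 2 lower regions (adjusted p = 0.23, Fisher's exact test), both near Prrx1. None of the 8 sex-linked genes found in the reference had a listed region.

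**Figure D3:**
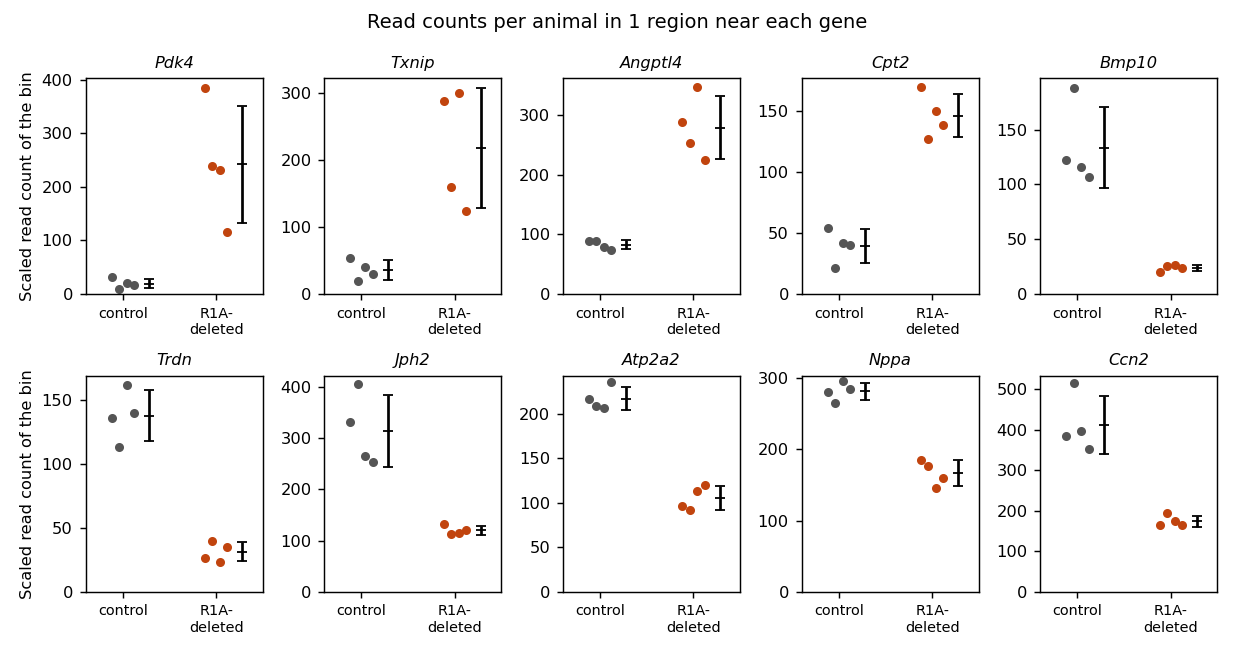
Scaled read counts of the bin in each of 4 control (grey) and 4 R1A-deleted (orange) animals for 1 region near each of 10 genes, with the mean and SD as a bar beside the points and each vertical axis starting at 0. The groups do not overlap in any panel: Pdk4, Txnip, Angptl4 and Cpt2 are higher in R1A-deleted animals, and Bmp10, Trdn, Jph2, Atp2a2, Nppa and Ccn2 lower.

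Single genes often gathered many regions of a single direction. Myo18b, an unconventional myosin, had 43 higher regions and none lower, Tacc2 39 higher, and Pam 32 lower, followed by Atp2a2 and Ryr2. The regions with the smallest adjusted p in Myo18b and Tacc2 rose by 2.51 ± 0.34 and 1.89 ± 0.29 log2 (SE), and that in Pam changed by -1.27 ± 0.23. Of 119 genes with at least 5 regions, 50 had only higher and 29 only lower ones, 79 together, against a mean of 10.3 and a highest value of 24 in 10000 shuffles of direction. Windows of 1 Mb behaved alike: 318 of 746 windows with at least 3 regions held a single direction, against a mean of 137.4 after shuffling (permutation p = 1e-05, the smallest it can give), but windows of 5 Mb did not (33 of 444 against 28.3, permutation p = 0.2).

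Direction also differed by place. Bins within 1 kb of a gene end made up 9.3% of higher and 6.2% of lower regions (odds ratio 1.55, two-sided Fisher's exact p = 9.5e-05), while 61.0% and 60.6% lay inside genes (odds ratio 1.02, p = 0.77, Fisher's exact test). On chromosome X, 40 of 70 regions were lower, 57.1% against 33.1% on the autosomes (odds ratio of being higher 0.37, adjusted p = 0.00056 over chromosomes, Fisher's exact test), and on chromosome 10, where Trdn and Gja1 lie, 46.5% were (adjusted p = 2.3e-05). Lower regions were also more frequent on chromosomes 13 (43.5%, adjusted p = 0.0084) and 12 (41.3%, 0.03), and less frequent on 5 (25.2%, 0.0016), 7 (24.9%, 0.0016) and 4 (26.2%, 0.026). These tests count regions as independent. Without the gene with the most regions on each chromosome, X (39 of 65, adjusted p = 0.00027) and 10 (43.7%, 0.0013) kept the call, while 13, 12, 5, 7 and 4 lost it (adjusted p from 0.081 to 0.18), 5 without Myo18b (28.2%) and 7 without Tacc2 (27.7%), and 11 gained 1 (26.0%, 0.023). On chromosome 1, which carries Prrx1, 35.6% were lower (adjusted p = 0.5). All 12 regions on chromosome Y were higher and lay between 90727001 and 90827750. Across regions, which are not independent replicates, larger authors' fold changes went with wider regions (Spearman's rho 0.48 for higher and 0.38 for lower regions; permutation p = 1e-05 each, the smallest it can give). Listed regions are merged, and a larger change may let more neighbouring bins pass, so width and fold may be tied by construction. Larger fold changes also went with lower mean counts (-0.46 for both). The selection of called regions gives this by itself, since a bin with few reads is listed only if its change is large.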

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

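Which animals stood apart in a named region was decided by a rule fixed before the data were examined, and no explanation was tested. Each value is the scaled read count of 1 animal that lay far from the other 3 of its group, and 10 of 162 groups met the rule (2 for each of 80 named regions and 2 for listed reads per animal), where chance alone gives about 5.0% of groups.

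In the region nearest to Prrx1, control 1 was lowest with 48.6 (the others 56.5 to 57.3), far above every R1A-deleted animal. Near Slco4a1 and Mir133a-2, control 4 was lowest with 88.1 (118.0 to 123.0). Near Anxa10, control 2 was highest with 117.6 (78.3 to 80.5). In the broad Tpm1 region, R1A-deleted animal 2 was lowest with 89.5 (127.9 to 134.3). Near Cntn2, control 1 was lowest with 24.8 (33.6 to 35.3). Near Myh7, control 4 was highest with 406.5 (363.6 to 364.8). In Fbln1, control 3 was lowest with 72.7 (86.6 to 89.4). Near Foxd3, control 3 was highest with 29.4 (14.1 to 16.4), and R1A-deleted animal 3 was highest with 71.9 (46.4 to 48.7). Near Id2, control 2 was lowest with 63.5 (91.9 to 94.0). Control 2 had the fewest listed reads, 151976.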

How the results depend on the processing

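The authors' scale, leaving out the gene with the most regions and the random-gene permutation were chosen after the data were seen; the other alternatives were fixed before. The excess of higher regions near gene ends (odds ratios 1.21 to 1.77) kept its direction and call in every setting run for it. So did the 2 lost regions near Prrx1 and the other named lower regions, but 1771 to 1776 of all 1776 lower regions did too, because only called regions are listed, so this tests nothing. The count of higher regions was 3551 with edgeR on the authors' scale, with DESeq2 on that scale, with repeat libraries apart and with the block, against 988 with TMM, 987 with RLE, 921 with TMM and libraries apart and 861 with DESeq2's own factors; lower calls were 1776 in each of these. Leaving out each animal gave 606 to 1087 higher calls with TMM, the lowest without R1A-deleted animal 1 (606) and animal 2 (625), and 3549 to 3551 on the authors' scale. Of 80 named regions, 13 of the 47 higher ones lost their call with TMM and none turned. Neither scale tests the split of directions, because TMM shifts a mostly higher table downward and the authors' scale follows the authors' fold changes. The low-count filter removed 0 regions and tests nothing. Animals of the same number gave correlations of deviations of 0.26, 0.04, -0.04 and 0.00. The value of control 1 with R1A-deleted animal 1 stood out, since all other pairs lay between -0.15 and 0.08. What these 2 animals share is not known, and the other numbers showed no pairing. The replicate block gave 1111 higher and 1776 lower calls with TMM. The real split gave 2764 calls with TMM and the highest other of 35 splits 0, so 1 split reached the real count; since regions were listed for passing the real split, this count says nothing about chance.

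Smaller counts follow from stricter criteria: an authors' adjusted p under 0.01 left 1932 higher and 771 lower, an absolute log2 change of at least 1 left 725 and 243, and mean counts at or above the median left 1875 and 795. Within 1000 kb of Prrx1 there were 5 regions, and 33 windows of 5 Mb held a single direction.

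For gene lists (odds ratios of being higher), the cause was not tested. With 1 region per gene the calls were lost for sarcomere (0.461), calcium (0.535), transcription factors (0.902), atrial (0.219), ventricular (0.21), stress (0.242) and TGF-beta (0.408), while ion channels (1.23) and junctions (0.717) turned. Within 1 kb of a gene end, calls were lost for ion channels (0.331), calcium (0.0659), atrial (0.108), ventricular (0.331) and TGF-beta (0.111). Transcription factors (1.01) and metabolism (0.855) turned. Few regions remained there: calcium had only 2 lower, TGF-beta only 1 lower and transcription factors only 1 higher. Those 3 values come mostly from the added constant. With an authors' adjusted p under 0.01, ion channels (0.446) and ventricular (0.47) lost the call and metabolism (3.64) gained it. Smooth muscle (0.239) turned on 1 higher and 2 lower regions, and adipocyte markers (1.2) on 1 higher region alone. At or above the median count, transcription factors (0.642) and ventricular (0.422) lost the call, and adipocyte markers (2.12) turned on 2 higher regions alone. Within 50 kb, transcription factors (0.683) lost it and junctions (0.953) turned. Without the gene with the most regions, transcription factors (0.634) and ventricular (0.651) lost it, and smooth muscle (0.701) and junctions (0.901) turned. Against random genes, the calls of sarcomere (0.351), ion channels (0.394), calcium (0.143), transcription factors (0.462) and ventricular (0.313) were lost, with adjusted p of 0.23, 0.72, 0.2, 0.2 and 0.51 by permutation, and those of the atrial, stress and TGF-beta lists were kept.

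Not run were an adjusted p under 0.1, since no listed value exceeds 0.05, motif counts, which need a genome, and a pseudocount, which counts do not need. Listed reads per library are not depth, so how far depth limits the authors' calls is unknown.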

Other observations

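The tests of cardiomyocyte share, scaling, ventricular tissue and sex were chosen after their results were seen; those of clock genes, fasting and glucocorticoid targets, single animals and matched counts were written before theirs, though after the patterns were noticed. Further targets of fasting and glucocorticoid signalling, listed before their values were looked at, were nearly all higher in R1A-deleted atria. Of 22 genes, 20 had a listed region, with 29 higher and 3 lower regions. The metallothionein genes Mt1 and Mt2 had 4 and 1 higher regions, the cell cycle inhibitor Cdkn1a 3, and the glucocorticoid-induced genes Tsc22d3, Klf9 and Dusp1 2 each. Hif3a and Acot1 had 2 higher regions each, and Trim63, Slc25a20 and Slc22a5 1 each. The insulin signalling genes Insr and Irs2 had 1 lower region each, and Sgk1 2 higher and 1 lower. Zbtb16, induced by glucocorticoids in many tissues, had 18 higher regions and none lower, and the strong gain nearest to Armc12 lay 26.1 kb from Fkbp5, another such gene. Zbtb16 and Fkbp5 were picked after their values were seen.

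Other genes with many regions of a single direction were not in the fixed lists. Higher only were Gse1 (13), Camta1 (9), Tns1 (9) and Dysf (8), the membrane repair gene of muscle. Lower only were Rhobtb1 (13), Akap6 (10), which anchors signalling enzymes at the nuclear envelope and reticulum of myocytes, Slc38a2 (9) and Psd3 (9). Clock output genes were higher at 6 of 6 regions, 3 of them at Tef and 1 each at Per2, Hlf and Ciart.

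Regions near calcium handling and atrial genes were mostly lower, with a median authors' log2 change -1.38 (calcium) and -1.49 (atrial) from that of the other listed regions, of which only the atrial one passed against random genes (adjusted p = 0.35 and 0.034 by permutation). A scaling error would move all regions alike. Added to a spread between regions, it could still leave both directions within a list. The mixture seen (21 higher and 72 lower for calcium, 11 and 56 for atrial) therefore does not count against it. How far scaling shaped the lean of either list stays open. Only called regions are listed, so these medians largely restate the split by direction, and unlisted regions of the same genes cannot be seen. Fewer cardiomyocyte nuclei in the R1A-deleted samples would lower all cardiomyocyte genes. Of the 259 regions near sarcomere, channel and calcium genes, 35.5% were higher, those of Ttn among them. That share lies below the 66.7% of all listed regions, a lean that fewer such nuclei would also give. With TMM, 90 of the 92 higher ones stayed above 0, but TMM turned only 154 of all 5327 listed regions, so this adds nothing. Although nuclei were sorted for PCM1, a smaller share as a partial source stays open: 21 of 29 regions near markers of other cell types were higher, 72.4% beside 66.7% of all listed regions, with endothelial markers split 4 and 4. Ventricular tissue in the dissections and an effect of the allele both stay open: 38.1% of ventricular list regions were higher, which did not pass against random genes (permutation p = 0.19), although all 3 regions of Myl2 and Myh7 were lower.

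Regions near fatty acid and fasting genes were mostly higher, although the fixed metabolism list, at 76.3% against 66.6% of all other regions, did not pass (adjusted p = 0.24 by Fisher's exact test, 0.72 against random genes). A fasting or glucocorticoid state that differed between the groups of animals is a candidate explanation. The further targets were higher at 90.6% of regions (odds ratio 4.87, two-sided Fisher's exact p = 0.0024), against an average of 68.4% for random genes (permutation p = 0.03). Fisher's test counts regions as independent. The permutation ignored gene position, although 1 Mb windows often held a single direction. Whether further targets adjoin each other or genes of the metabolism list was not checked. The labels give no feeding state, hour or stress of the animals, so such a state and an effect of the allele itself cannot be separated here. The hour of collection stays open, because clock output genes and genes of the opposite phase (2 higher at Npas2, 1 lower at Nfil3) gave no call on so few regions (two-sided Fisher's exact p = 0.33). On the authors' scale 100% of the 45 higher metabolic regions stayed higher without any 1 animal, and all 45 still passed edgeR. So did 3549 to 3551 of all 3551 higher regions. Regions were listed for passing on these same animals, so the prediction written for this test could not separate the cases. Whether 1 animal shaped which regions were listed stays open.

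Regions on chromosome X were lower more often than elsewhere, 57.1%, as were those on chromosome 10, and both kept this without their gene with the most regions (adjusted p = 0.00027 and 0.0013, Fisher's exact test). These tests count regions as independent, and only 1 gene per chromosome was left out. Gja1 on chromosome 10, with 8 lower and 2 higher regions, stayed in. Autosomal regions matched on mean count were lower in 34.4% on average (one-sided permutation p = 0.0002), which argues against read counts as the cause. Unequal sexes in the groups stay open. Of X bins, 0.35% were listed against 0.66% on the autosomes, which argues against a broad difference in X reads. None of the 8 sex-linked genes found in the reference had a listed region, which goes against more males in 1 group. The filter on bins is not known, so this does not settle it. All 12 listed Y regions were higher, against the lean of X, but lay in 1 stretch at its distal end (90727001 to 90827750). Whether that stretch is carried by males alone was not checked, so it does not tell the sexes apart. No biological explanation was tested.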
